A study of Mus musculus with 6 samples.

How the data were processed

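The data were mRNA sequencing libraries of cultured mouse bone marrow-derived macrophages, 3 from cells given M-CSF and RANKL (Ctrl) and 3 from cells given the same factors with 10 uM ZM. Groups and replicate numbers were taken from the sample labels, and every column of the deposited table was matched to a sample by its name. Per the labels, the libraries were made from TRIzol-extracted RNA with a commercial mRNA-seq kit and carried a common batch label. No vehicle in the Ctrl cultures was named.

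The deposited table held, for 26106 genes with at least 1 count over the 6 libraries, whole-number counts per gene and library that the authors had not normalized. Per the submitters' processing notes, HISAT2 2.2.1, featureCounts 2.0.3, Subread, DESeq2 and the mouse build mm10 were used; the notes as used here gave no role or order. The annotation release, the strand setting of the counting and any filter were not given in the sources used here. Among counts of 1 to 20, between 72.7% and 76.4% were even in each library, the pattern left when both mates of a read pair are counted, so the number of sequenced fragments is below the total counts printed here. The deposited FPKM values were the authors' counts divided by gene length and by the column total. The gene length recovered from them was whole within 0.001 bases, and the same in each library with a count, for 26106 genes. The FPKM values served only for these lengths and entered no test. The 156 entries without a symbol held 0.0024% of all counts; they carried gene identifiers and stayed in the tests.

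Gene positions are from GENCODE M21 on GRCm38, the assembly that mm10 names, joined by gene identifier; 25680 identifiers (98.4%) were found there. Exons of 15 of the 71 genes singled out by the rule given here overlapped exons of another annotated gene. Without a stated strand setting, reads in such overlaps cannot be assigned with certainty, and the overlaps with well-covered partners are given beside the genes concerned. Where 2 entries had 1 symbol, the more abundant entry stood for a list member.

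Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group, which left 15590 genes and 99.95% of the counts. Composition factors were computed by TMM, and the quasi-likelihood F test was fitted on group alone. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and a second count required a log2 fold change of at least 1 in size. Levels are CPM as computed by the cpm function of edgeR on the TMM-scaled library size, given as mean ± SD of 3 libraries. Fold changes are ZM against Ctrl, and the standard error of a log2 fold change (SE) is its size over the square root of the F statistic. A gene or list is said to have risen, fallen or changed only where its adjusted p was under 0.05. The model, the lists, the rule for named genes and most alternatives were chosen before the data were examined.

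The 37 gene lists covered osteoclast formation and function, macrophage identity, inflammation, metabolism, stress responses, signalling targets and markers of other bone marrow cell types. The 32 lists with at least 5 tested members were tested against all other genes with camera (limma 3.58.1) on the edgeR fit, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 32 lists. An estimated correlation per list, fry and fry's mixed test were run beside it. Member counts are given with adjustment over all genes tested and with adjustment over the list alone. Named genes were 18 genes fixed in advance; the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 CPM, non-overlapping groups and an assigned symbol; up to 3 members with the smallest adjusted p from each called list and from the first 5 lists; and the most abundant marker of each other cell type. Together these were 71 genes.

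Shares of counts were compared by an exact two-sided permutation test of the difference of means, for which 3 against 3 libraries allow no p under 0.1.

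Alternatives were size factors as in DESeq2 (RLE), no composition factor, upper-quartile factors, no filter, at least 1 CPM in all libraries, DESeq2 1.42.0, limma-voom, robust edgeR estimation, glmTreat against a log2 fold change of 0.5, the replicate number as a block, a loess offset (span 0.5) removing each library's trend with gene length, that offset with the block, each library left out in turn, and the 20 most abundant genes left out. For lists, a background of genes at 10 CPM or more was also used; robust estimation and glmTreat do not enter camera. Alternatives meant for normalized values were not needed. Counts divided by 2, limma-voom with library quality weights, and the shares of Rn18s, Malat1 and Lyz2 were added after the data had been seen.

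The analysis was tested on simulated counts with the means and library sizes of the 15590 genes in Ctrl against ZM, 100 genes changed at each of 2 fold sizes and 1 list of 15 genes lowered together. The edgeR test recovered 52% of genes changed by a log2 fold of 1 and 84% of those changed by 2, with 12 false calls (7.64% of calls). DESeq2 recovered 67% and 89% with 49 false calls (22.7%). The planted list was called and 0 of 36 unchanged lists were. Simulated genes were drawn independently of each other, with the same dispersion in both groups. In the data the estimated inter-gene correlation was 0.14 for bone resorption and 0.93 for S phase. The simulation therefore does not show how often lists of correlated genes are called in error. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.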

Results

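The series measured the transcriptome of bone marrow-derived macrophages from 6-week-old male C57BL/6 mice, the precursor cells from which osteoclasts, the bone-resorbing cells, form. Cells were cultured for 2 days with 10% serum and the cytokine pair that drives osteoclast formation, RANKL at 100 ng/mL together with M-CSF at 30 ng/mL. Ctrl cells (n = 3) had no further addition named, and ZM cells (n = 3) were given 10 uM ZM-306416, a kinase inhibitor of VEGF receptors. Total counts were 45512004, 49613493 and 49444812 in Ctrl replicates 1, 2 and 3, and 54256377, 51329237 and 51356084 in ZM replicates 1, 2 and 3. Nothing in the labels says that the 3 libraries of a group came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.

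The Ctrl libraries lay closer together than the ZM libraries. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.992 for the Ctrl pairs and 0.968 to 0.987 for the ZM pairs. Counts of same-group libraries differed by more than sampling noise in every pair, with chi-square per degree of freedom from 5.93 to 8.75 in Ctrl and from 46.7 to 219 in ZM, so no library was present under 2 names. On the principal component that held 65.8% of the variance, the Ctrl libraries lay between -43.6 and -37.4, and ZM replicates 1, 2 and 3 at 28.3, 4.29 and 87.8. ZM replicate 3 thus stood apart, also by its TMM factor of 0.919 against 0.995 to 1.03 in the other libraries.

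The comparison of ZM with Ctrl asked which transcripts the inhibitor altered in cells stimulated to form osteoclasts. By camera with its preset correlation, the lists of bone resorption and of precursor fusion were lower with ZM, and those of macrophage identity and of the oxidative stress response were higher. With an estimated correlation none of these passed, at adjusted p = 0.158, 0.331, 0.465 and 0.331 in that order. With fry each of them passed, at adjusted p = 0.00412, 0.0133, 0.0327 and 0.0278 in the same order. Cathepsin K (Ctsk), the collagen-degrading protease of osteoclasts, fell from 1009 ± 51.7 to 123 ± 36.2 CPM, whereas Cx3cr1, the fractalkine receptor of monocytes and macrophages, rose from 65.2 ± 0.876 to 164 ± 7.10 CPM (SD, n = 3 per group). Of 15590 genes tested, 1711 changed (10.975%). Of these, 863 rose and 848 fell, and 277 of the risen and 460 of the fallen genes changed by a log2 fold of at least 1. The groups did not overlap for 3347 genes higher and 3339 lower with ZM, 42.9% of those tested, where chance gives 10%. The count was lower without any 1 Ctrl library or ZM replicate 1, with 180, 224 and 148 genes called without Ctrl replicates 1, 2 and 3 and 669 without ZM replicate 1. It was higher without ZM replicates 2 and 3, with 5023 and 3120 genes, of which 1707 and 1701 were among the 1711. DESeq2 called 3295 genes, the 1711 among them, and a test against a log2 fold of 0.5 called 302, of which 70 rose and 232 fell. That stricter test did not call 32 of the 61 named genes called here, among them Adgre1 (0.385), Sdha (0.673) and Uqcrc2 (0.904).

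Among called genes with a mean of at least 10 CPM, non-overlapping groups and an assigned symbol, the largest falls were those of Kbtbd11, Mst1r, Cyp2s1, Scin, Slc9b2, Prrg4, Myo1d, Plxna4, Ctsk and Acp5. Kbtbd11 dropped from 66.6 ± 5.23 to 3.52 ± 1.81 CPM (log2 fold -4.23, adjusted p = 0.00253). Mst1r, the receptor for macrophage-stimulating protein, dropped from 19.0 ± 0.801 to 1.08 ± 0.644 CPM (adjusted p = 0.00392), and Scin, which encodes an actin-severing protein, from 63.2 ± 3.77 to 5.56 ± 3.38 CPM (adjusted p = 0.00900). Slc40a1, the iron exporter ferroportin, had the largest rise within the same limits, from 13.03 ± 1.56 to 90.9 ± 77.7 CPM (log2 fold 2.80, SE 0.55, adjusted p = 0.0240), with 180.6 CPM in ZM replicate 3 against 45.4 and 46.7 CPM in ZM replicates 2 and 1. Mcemp1, Tmem176a, Tmem176b, Arl5c, Marcksl1, C1qa, Selenop, Csf3r and C1qb followed, with log2 folds from 2.57 for Mcemp1 to 2.12 for C1qb. Without ZM replicate 3 the log2 fold of Mcemp1 was the highest of these at 2.19, with 1.94 for Tmem176a, 1.85 for Marcksl1, 1.82 for Slc40a1 and 1.79 for Tmem176b. It was 1.57 for C1qa, 1.55 for Arl5c, 1.48 for C1qb, 1.43 for Csf3r and 1.28 for Selenop. C1qa and C1qb, which encode chains of complement C1q, rose from 82.1 ± 5.42 to 369 ± 218 CPM and from 200 ± 12.1 to 867 ± 541 CPM. Exons of Tmem176a and Tmem176b overlap by 81 bases on opposite strands, so their separate levels are uncertain. Among these 20 genes, Kbtbd11, Mst1r, Cyp2s1, Slc9b2, Myo1d, Ctsk, Acp5, Mcemp1 and Marcksl1 kept the call without any single library. Scin lost it without Ctrl replicate 3 (0.0548), and Tmem176a without Ctrl replicates 1 and 3 (0.0545 and 0.0585). Without any 1 of the 3 Ctrl libraries the adjusted p was 0.0649 to 0.0747 for Tmem176b, 0.0796 to 0.0925 for C1qa, 0.0940 to 0.106 for C1qb, 0.0974 to 0.104 for Arl5c, 0.105 to 0.121 for Slc40a1 and 0.111 to 0.121 for Csf3r. Prrg4, Plxna4 and Selenop lost the call without each Ctrl library and also without ZM replicate 1, with adjusted p of 0.0962 to 0.124, 0.0949 to 0.121 and 0.0517 to 0.150. The log2 folds of Prrg4 and Plxna4 were -3.11 and -3.06, and -3.95 and -3.70 without ZM replicate 2. Without ZM replicate 3 they were -2.60 and -2.56.

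Bone resorption genes were lower with ZM as a list by camera with its preset correlation (mean log2 fold -1.49, adjusted p = 6.5e-19), but not with an estimated correlation (adjusted p = 0.158). With fry the list passed (adjusted p = 0.00412). Of 16 tested members of the list, 12 fell, 0 rose and 4 were not called, and the counts were the same adjusted over the list alone. Ctsk (ENSMUSG00000028111, a protein-coding gene at 95499256 to 95509362 on chromosome 3 of GRCm38, forward strand) was 8.23-fold lower with ZM (log2 fold -3.04, SE 0.23, adjusted p = 0.00153). Acp5 (ENSMUSG00000001348, chromosome 9, 22126727 to 22135711, reverse strand), which encodes tartrate-resistant acid phosphatase, dropped from 841 ± 46.2 to 103 ± 31.7 CPM (log2 fold -3.02, SE 0.23, adjusted p = 0.00153). Mmp9 (ENSMUSG00000017737, chromosome 2, 164940780 to 164955850, forward strand), a matrix metalloproteinase, was at 2078 ± 38.1 CPM in Ctrl and 262 ± 127 CPM in ZM (log2 fold -2.99, SE 0.38, adjusted p = 0.00654). Slc9b2, a sodium-proton exchanger, fell from 74.3 ± 4.71 to 8.18 ± 3.42 CPM and Ckb, the brain-type creatine kinase, from 633 ± 40.3 to 263 ± 28.9 CPM. Calcr, the calcitonin receptor, was at 0.807 ± 0.373 CPM in Ctrl and 0.0873 ± 0.0931 CPM in ZM, with 0 counts in ZM replicate 3. Relative to the Ctrl mean, the list mean was -1.30, -1.37 and -1.88 in ZM replicates 1, 2 and 3. Acp5, Ctsk, Mmp9, Slc9b2 and Ckb kept the call without any single library. That of Calcr (adjusted p = 0.0494) was lost without each library but ZM replicate 3 (0.0530 to 0.190), without composition factors (0.0534), with limma-voom (0.0585), with robust estimation (0.0515), without the 20 most abundant genes (0.0502) and against a log2 fold of 0.5 (0.1405).

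**Figure D1:**
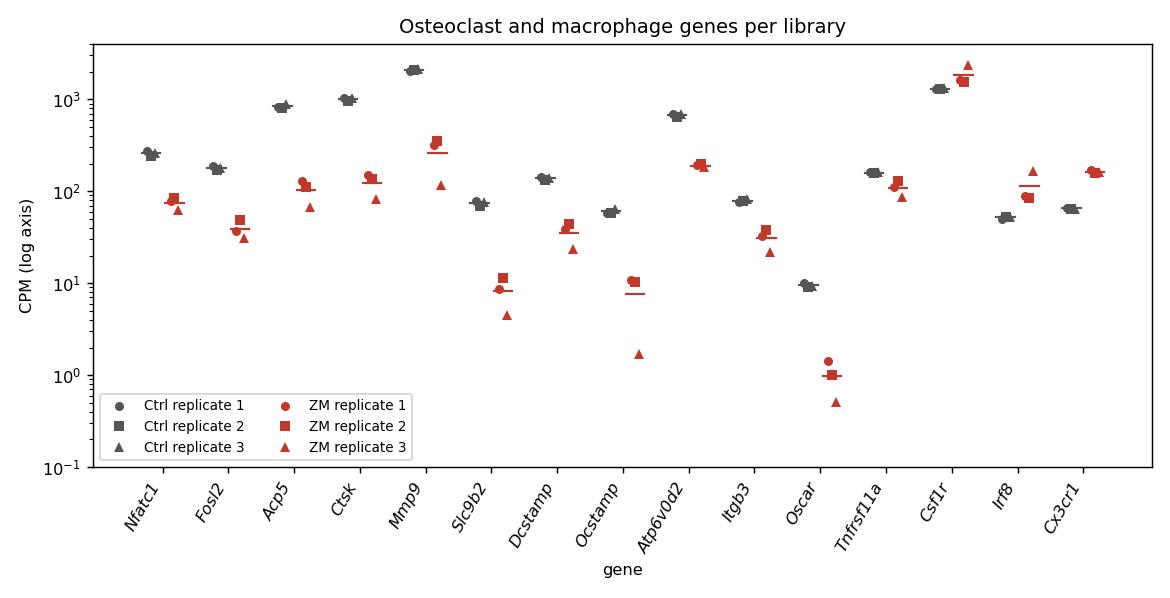
Points show CPM on a log axis in each of the 3 Ctrl libraries (grey) and 3 ZM libraries (red) for 15 osteoclast and macrophage genes, with the group mean as a bar and the symbol giving the replicate. All 3 ZM points of Ctsk lie between 81.4 and 149 CPM, under the Ctrl points at 950 to 1043 CPM, and those of Cx3cr1 lie between 157 and 171 CPM, over the Ctrl points at 64.5 to 66.1 CPM.

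Genes for the fusion of precursors into multinucleated cells showed changes in both directions, with a lower mean of the list. Of 14 tested members, 7 fell, 3 rose and 4 were not called, the same adjusted over the list alone. Dcstamp (ENSMUSG00000022303, chromosome 15, 39745930 to 39760938, forward strand), a membrane protein needed for fusion, dropped from 138 ± 5.48 to 35.4 ± 10.6 CPM (log2 fold -1.96, adjusted p = 0.00443). Atp6v0d2 (ENSMUSG00000028238, chromosome 4, 19876841 to 19922605, reverse strand), a proton pump subunit with a role in fusion, was 3.53-fold lower, at 671 ± 24.9 CPM in Ctrl and 190 ± 7.57 CPM in ZM (SE of the log2 fold 0.09, adjusted p = 9.2e-04). Ocstamp, another fusion protein, fell from 60.4 ± 3.70 to 7.63 ± 5.14 CPM (adjusted p = 0.0224). Sh3pxd2a, a podosome scaffold, fell from 117 ± 7.90 to 36.1 ± 12.1 CPM (adjusted p = 0.00830), and Itgb3, the integrin beta chain of the osteoclast vitronectin receptor, from 79.3 ± 3.73 to 30.8 ± 8.30 CPM (adjusted p = 0.00915). The list mean was -0.94 (camera adjusted p = 4.2e-05; adjusted p = 0.331 with an estimated correlation), and -0.87, -0.74 and -1.48 in ZM replicates 1, 2 and 3. Without a single library, Ocstamp lost the call for any Ctrl library or ZM replicate 1 (0.0586 to 0.0999), Itgb3 for any Ctrl library (0.0527 to 0.0608) and Sh3pxd2a for Ctrl replicate 1 (0.0518).

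Among osteoclast transcription factors, 6 of 17 tested members fell, 2 rose and 9 were not called, with the same counts adjusted over the list alone. Nfatc1 (ENSMUSG00000033016, chromosome 18, 80606205 to 80713071, reverse strand), the master regulator of osteoclast formation, fell from 260 ± 14.4 to 75.2 ± 10.8 CPM (log2 fold -1.79, SE 0.13, adjusted p = 0.00153). Fosl2, an AP-1 subunit, fell from 180 ± 8.85 to 38.9 ± 8.92 CPM and Ppargc1b, a coactivator of mitochondrial biogenesis, from 26.7 ± 1.88 to 7.26 ± 1.48 CPM. The calls of Nfatc1, Fosl2 and Ppargc1b held without any single library. Fos, the AP-1 subunit required for osteoclast formation, was at 215 ± 12.1 CPM in Ctrl and 174 ± 48.1 CPM in ZM, a difference that was not called (adjusted p = 0.315). The list mean was -0.53 (camera adjusted p = 1.2e-04; adjusted p = 0.465 with an estimated correlation and 0.0820 with limma-voom and quality weights). It was -0.47, -0.39 and -0.86 in ZM replicates 1, 2 and 3.

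Receptors and adaptors upstream of these factors were mostly not called. Of 15 members of the list of RANK and co-stimulatory receptor signalling, 1 fell, 0 rose and 14 were not called, or 2 fell and 3 rose adjusted over the list alone. The fallen gene was Oscar, a collagen-binding co-stimulatory receptor, at 9.54 ± 0.537 CPM in Ctrl and 0.976 ± 0.460 CPM in ZM (adjusted p = 0.00312), which kept its call without any single library. Tnfrsf11a, which encodes the RANKL receptor RANK, was at 160 ± 3.09 CPM in Ctrl and 109 ± 21.1 CPM in ZM (log2 fold -0.55, SE 0.14), just over the threshold at adjusted p = 0.050008. It was under the threshold in 14 of 21 alternatives, with adjusted p of 0.0118 and 0.00655 without ZM replicates 2 and 3, 0.108 without ZM replicate 1 and 0.161 to 0.183 without single Ctrl libraries. Fcer1g, a signalling adaptor, was at 439 ± 6.98 and 812 ± 297 CPM (log2 fold 0.89, adjusted p = 0.0519). For Fcer1g the adjusted p was 0.173 to 0.183 without single Ctrl libraries and 0.102, 0.00959 and 0.00518 without ZM replicates 1, 2 and 3, and the log2 fold was 0.56 without ZM replicate 3. Fcer1g was under the threshold in 9 of 21 alternatives, among them the replicate number as a block (0.0336). The list as a whole was not called (mean -0.15, camera adjusted p = 0.490), and its mean turned to 0.06 when at least 1 CPM was required in all libraries and to 0.08 against a background of genes at 10 CPM or more. Both of these limits left out Oscar.

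Repressors of osteoclast formation changed in both directions: 5 of 12 rose, 2 fell and 5 were not called, or 7 rose and 4 fell adjusted over the list alone. Irf8, which represses Nfatc1, was higher with ZM at 113 ± 46.4 against 52.1 ± 1.34 CPM (log2 fold 1.12, and 0.73 without ZM replicate 3; adjusted p = 0.0353). Id1, an inhibitor of DNA binding, was at 13.2 ± 1.98 against 7.15 ± 0.204 CPM (adjusted p = 0.0128). Tnfrsf11b, the RANKL decoy receptor osteoprotegerin, fell from 0.513 ± 0.177 to 0.0255 ± 0.0441 CPM (adjusted p = 0.0309) and had 0 counts in ZM replicates 1 and 3. The list mean was 0.05 and its median 0.42 (camera adjusted p = 0.154), and the highest mean in any alternative was 0.44. Tnfrsf11b, under 1 CPM in both groups, entered the mean of 0.05 with a log2 fold of -4.18. Camera placed the list upward in every setting, also where the mean was negative. The mean turned to -0.003764 without ZM replicate 3, where the list was called upward (adjusted p = 0.0141), and to -0.001068 with the length offset and block, where it was also called upward (0.0346). The mean was -0.19 without ZM replicate 2 (0.1004), the adjusted p was 0.146 to 0.183 without any other library, and the list was also called without a filter (0.0445). Without single Ctrl libraries the adjusted p was 0.134 to 0.151 for Irf8, 0.0747 to 0.0842 for Id1 and 0.109 to 0.141 for Tnfrsf11b. Without ZM replicate 1 it was 0.0625 for Irf8 and 0.0828 for Tnfrsf11b.

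Macrophage identity genes rose: 13 of 20 tested members rose, 0 fell and 7 were not called, with 15 risen and 0 fallen adjusted over the list alone. Cx3cr1 was 2.52-fold higher (log2 fold 1.33, adjusted p = 0.00126). Adgre1, which encodes the F4/80 antigen, rose from 442 ± 10.9 to 677 ± 41.0 CPM (adjusted p = 0.00921) and Marco, a scavenger receptor, from 1.1005 ± 0.0662 to 5.38 ± 2.38 CPM (adjusted p = 0.00938). Csf1r, the M-CSF receptor, was at 1306 ± 32.8 CPM in Ctrl and 1840 ± 447 CPM in ZM and was not called (log2 fold 0.49, adjusted p = 0.0920). For Csf1r the adjusted p was 0.231 to 0.264 without single Ctrl libraries, 0.124, 0.0286 and 0.0133 without ZM replicates 1, 2 and 3, and 0.0462 with DESeq2, and the log2 fold was 0.28 without ZM replicate 3. In the list of alternatively activated macrophages, 5 of 10 rose and 0 fell by both adjustments. Mgl2, a C-type lectin, rose from 0.372 ± 0.0759 to 3.48 ± 2.49 CPM (log2 fold 3.21, and 2.46 without ZM replicate 3; adjusted p = 0.0155). Mrc1, the mannose receptor and a member of both lists, rose from 91.3 ± 15.5 to 190 ± 60.5 CPM (adjusted p = 0.0330), and Egr2, a transcription factor, from 20.1 ± 1.22 to 30.3 ± 3.64 CPM (adjusted p = 0.0258). The list means were 0.95 for identity (camera adjusted p = 2.6e-11) and 1.15 for alternative activation (camera adjusted p = 6.7e-04), each with adjusted p = 0.465 with an estimated correlation. In ZM replicates 1, 2 and 3 the means were 0.68, 0.69 and 1.32 for identity and 0.76, 0.96 and 1.51 for alternative activation. The Ctrl libraries were further apart for alternative activation, at -0.26, 0.39 and -0.13 in replicates 1, 2 and 3, than for identity, at -0.05, 0.06 and -0.01. Cx3cr1 kept the call without any single library. Without single Ctrl libraries the adjusted p was 0.0685 to 0.0809 for Adgre1, 0.0594 to 0.0654 for Marco, 0.0796 to 0.0879 for Mgl2, 0.0921 to 0.149 for Mrc1 and 0.107 to 0.141 for Egr2. Egr2 also lost the call without ZM replicate 1 (0.0664). An exon of Csf1r overlaps Hmgxb3 by 873 bases on the opposite strand, and Hmgxb3 had 9475 counts against 472571. Cx3cr1 overlaps Gm33858 by 78 exonic bases on the opposite strand, and Gm33858 had 1334 counts against 34809.

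Genes of the oxidative stress response, many of them targets of the transcription factor Nrf2, rose in 13 of 17 cases with 0 fallen, and in 14 adjusted over the list alone. Gclm, a subunit of the enzyme that limits glutathione synthesis, rose from 114 ± 1.85 to 309 ± 76.3 CPM (log2 fold 1.44, adjusted p = 0.00482) and kept the call without any single library. G6pdx, the first enzyme of the pentose phosphate pathway, rose from 214 ± 4.24 to 385 ± 60.9 CPM and Srxn1, sulfiredoxin, from 217 ± 11.7 to 326 ± 11.9 CPM. In the integrated stress response, 6 of 18 rose and 0 fell, with 9 risen adjusted over the list alone. Among them, Atf5 rose from 14.2 ± 1.37 to 29.6 ± 5.92 CPM, Nupr1 from 10.8 ± 0.213 to 23.9 ± 6.97 CPM and Trib3, a pseudokinase, from 9.26 ± 1.65 to 17.2 ± 2.32 CPM. List means were 0.66 for oxidative stress (camera adjusted p = 6.1e-09) and 0.49 for the integrated stress response (camera adjusted p = 2.1e-04), each with adjusted p = 0.331 with an estimated correlation. They were 0.58, 0.48 and 0.86, and 0.54, 0.42 and 0.42, in ZM replicates 1, 2 and 3. Without single Ctrl libraries the adjusted p was 0.0700 to 0.0722 for G6pdx, 0.0683 to 0.0881 for Srxn1, 0.0643 to 0.0740 for Atf5, 0.0914 to 0.0999 for Nupr1 and 0.0630 to 0.107 for Trib3. Without ZM replicate 1 it was 0.0564 for Nupr1 and 0.0676 for Trib3. Atf5 overlaps Nup62 by 82 exonic bases on the opposite strand (6623 against 26857 counts) and G6pdx overlaps Ikbkg by 418 (90452 against 19949), so the levels of both are uncertain.

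Genes of the VEGF and EGF receptor family, which include the named target class of the inhibitor, fell in 5 of 12 tested cases with 0 risen, or 6 fallen and 1 risen adjusted over the list alone. Kdr (ENSMUSG00000062960, chromosome 5, 75932827 to 75978458, reverse strand), which encodes VEGF receptor 2, fell from 46.3 ± 5.43 to 14.2 ± 6.87 CPM (log2 fold -1.71, adjusted p = 0.0274). The ligands Pgf and Vegfc fell from 46.0 ± 1.76 to 13.4 ± 5.38 CPM and from 39.3 ± 2.75 to 12.2 ± 5.68 CPM. Hbegf, an EGF receptor ligand, fell from 2.84 ± 0.648 to 0.935 ± 0.324 CPM, and Egfr from 20.3 ± 0.655 to 13.1 ± 2.38 CPM. Flt1, which encodes VEGF receptor 1, was at 0.481 ± 0.0907 CPM in Ctrl and 0.2799 ± 0.187 CPM in ZM (adjusted p = 0.365). The list mean was -0.63 (camera adjusted p = 0.0191; adjusted p = 0.465 with an estimated correlation), and -0.51, -0.43 and -1.17 in ZM replicates 1, 2 and 3. Its call was lost without ZM replicate 2 (0.0649), with limma-voom (0.0562, and 0.0820 with quality weights), with the length offset (0.0714) and against a background of genes at 10 CPM or more (0.0669). Without single Ctrl libraries the adjusted p was 0.0926 to 0.119 for Kdr, 0.0659 to 0.0747 for Pgf, 0.0906 to 0.108 for Vegfc, 0.0644 to 0.120 for Hbegf and 0.148 to 0.152 for Egfr. Hbegf (0.0772) and Egfr (0.0889) also lost the call without ZM replicate 1, and Egfr with the length offset and block (0.0680).

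Interferon-stimulated genes and genes of oxidative phosphorylation were lower with ZM as lists by camera with its preset correlation, with means of -0.48 (adjusted p = 3.4e-04) and -0.23 (adjusted p = 0.00509). Neither passed with an estimated correlation, each at adjusted p = 0.588. Of 24 interferon-stimulated genes, 2 fell and 0 rose, or 8 fell adjusted over the list alone. The 2 were Ifi44, from 14.2 ± 2.30 to 5.95 ± 2.198 CPM (adjusted p = 0.0289), and Rtp4, from 115 ± 17.4 to 49.3 ± 23.3 CPM (adjusted p = 0.0439). Xaf1 was at 43.4 ± 4.04 and 27.5 ± 6.90 CPM and was not called (adjusted p = 0.0576, with 0.0318 and 0.0379 without ZM replicates 1 and 3 and 0.0632 to 0.208 without any other library). Xaf1 was under the threshold in 8 of 21 alternatives, among them DESeq2 (0.00853) and the replicate number as a block (0.0327). Of 23 genes of the respiratory chain and ATP synthase, 7 fell and 0 rose by both adjustments. Among them, Sdha fell from 488 ± 13.4 to 330 ± 36.8 CPM, Cyc1 from 147 ± 7.49 to 101 ± 11.7 CPM and Uqcrc2 from 181 ± 3.95 to 127 ± 11.4 CPM. The interferon list mean was -0.12 in ZM replicate 1 against -0.73 and -0.69 in ZM replicates 2 and 3, with -0.23 in Ctrl replicate 2. Without ZM replicate 2 neither list was called, at adjusted p of 0.0835 for interferon-stimulated genes and 0.149 for oxidative phosphorylation. The interferon list was also not called with fry (0.135) or with quality weights (0.0966). Without single Ctrl libraries the adjusted p was 0.0806 to 0.131 for Ifi44, 0.115 to 0.166 for Rtp4, 0.0989 to 0.119 for Sdha, 0.109 to 0.132 for Cyc1 and 0.111 to 0.127 for Uqcrc2.

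**Figure D2:**
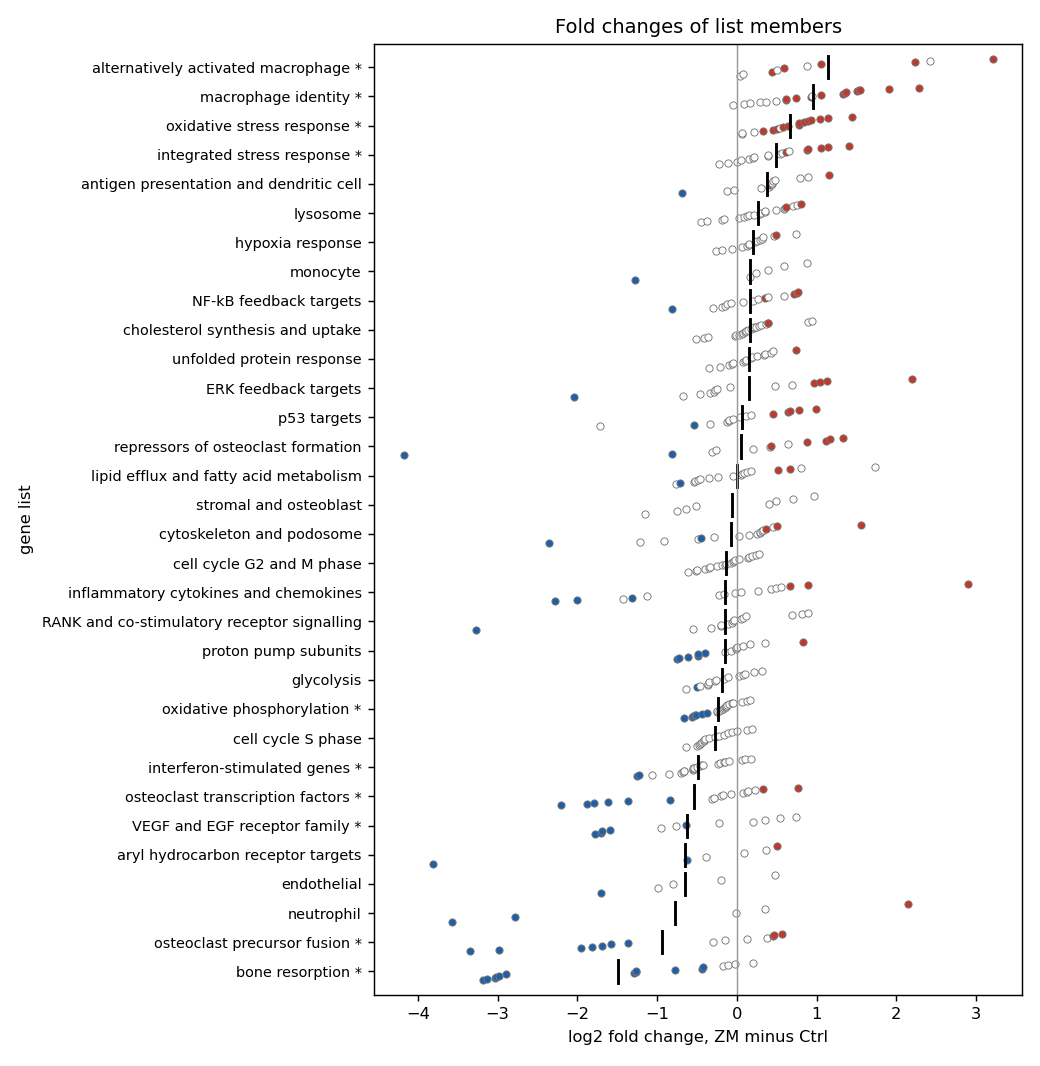
Each point is the log2 fold change of 1 tested list member, ZM against Ctrl, with filled red points for members that rose, filled blue points for members that fell, open points for members not called, a bar at the list mean and an asterisk at lists called by camera. Of the members of the bone resorption list, 12 are filled blue and 0 red, and of the macrophage identity list 13 are filled red and 0 blue.

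In all, 10 of the 32 lists tested were called by camera with its preset correlation, 4 upward and 6 downward. With an estimated correlation camera called 0 lists, while 4 had an unadjusted p under 0.05, and fry called 17. Those 17 included every list called by camera except that of interferon-stimulated genes (fry adjusted p = 0.135). Fry tests a list on its own and not against the other genes. The preset correlation also gave calls when Ctrl and ZM libraries were mixed: in the other splits of the 6 libraries into 3 and 3, between 5 and 12 lists were called, against at most 1 gene. Each of those splits had more Ctrl libraries on one side than on the other. Part of the difference of ZM from Ctrl thus remained, and the calls do not give a rate of false calls.

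Cell cycle genes did not pass the test in single genes: 0 of 18 S phase genes and 0 of 20 genes of G2 and M phase rose or fell, by both adjustments, with camera adjusted p of 0.148 and 0.530. The list means were -0.01, -0.03 and -1.06 for S phase and 0.01, 0.07 and -0.59 for G2 and M phase in ZM replicates 1, 2 and 3, so the lower level was in ZM replicate 3. The S phase list was called downward without ZM replicate 1 (0.0120) and, with all libraries, with the length offset and block (mean -0.40, adjusted p = 0.0465), while its mean was -0.02 without ZM replicate 3 (0.847) and the adjusted p without any other library was 0.103 to 0.175. Without ZM replicate 3 the mean of the G2 and M phase list turned from -0.13 to 0.05.

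**Figure D3:**
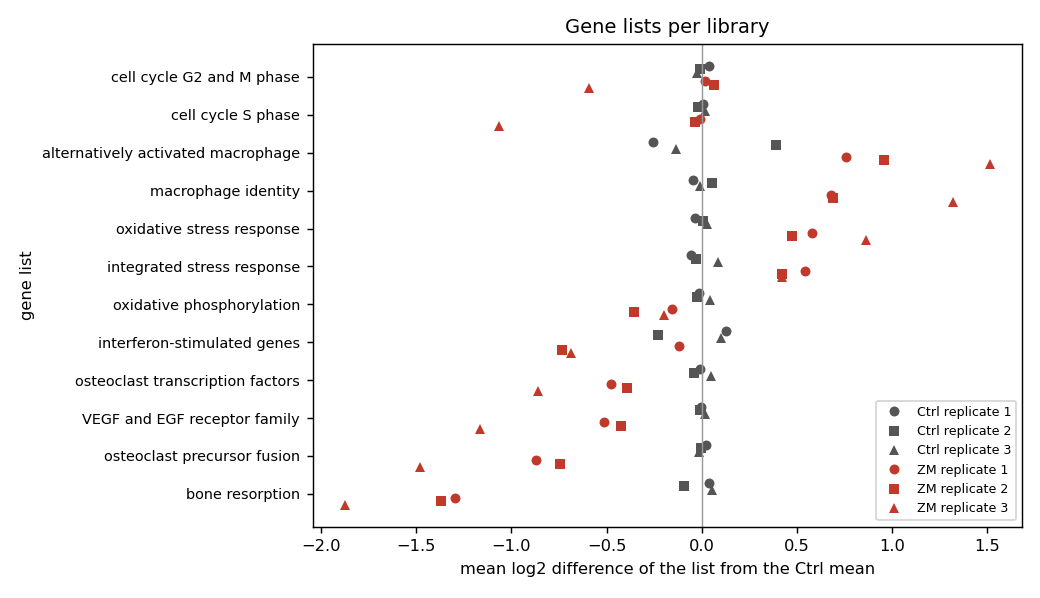
Points show the mean log2 difference from the Ctrl mean over the tested members of 12 lists, with each Ctrl library in grey, each ZM library in red and the symbol giving the replicate. All 3 ZM libraries lie between -1.88 and -1.30 for bone resorption and between 0.68 and 1.32 for macrophage identity, whereas for S phase ZM replicate 3 lies at -1.06 and ZM replicates 1 and 2 at -0.01 and -0.03.

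The acidification machinery and the lysosome were at the border of the test. Of 15 proton pump subunits, 6 fell and 1 rose by both adjustments (mean -0.15, camera adjusted p = 0.0701). Without ZM replicate 3 the mean was -0.23 and the list was called (0.00441), and without ZM replicate 2 it was -0.09 (0.354), with adjusted p of 0.0881 to 0.145 without any other library. Of 20 lysosome genes, 2 rose and 0 fell, or 7 rose and 2 fell adjusted over the list alone (mean 0.27, camera adjusted p = 0.0522). The lysosome list was called without Ctrl replicate 3 (0.0325), ZM replicate 1 (0.0328) or ZM replicate 2 (0.0104), and not without Ctrl replicate 1 (0.0795), Ctrl replicate 2 (0.0636) or ZM replicate 3 (0.138). Its mean leaned on ZM replicate 3: it was 0.12 without that library, and 0.17, 0.06 and 0.50 in ZM replicates 1, 2 and 3. Both lists were also called without composition factors, at 0.0403 and 0.0456, and without a filter, at 0.0399 and 0.00639. The lysosome list was called with the replicate number as a block (0.0222). Each of the 2 lists was called in 9 of 23 alternatives.

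Other metabolic lists, besides that of oxidative phosphorylation, were not called. In glycolysis, 1 of 15 fell and 0 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.161), and in the hypoxia response 1 of 15 rose and 0 fell (4 and 0; 0.148). In cholesterol synthesis and uptake, 2 of 23 rose and 0 fell (3 and 0 adjusted over the list alone; 0.154), and in lipid efflux and fatty acid metabolism 2 of 18 rose and 1 fell (4 and 4; 0.733), with a list mean of 0.01 that camera placed downward and that was from -0.0669 to 0.0304 without single libraries. The unfolded protein response had 1 risen gene of 16 and 0 fallen (2 and 0 adjusted over the list alone; 0.156), and of 6 targets of the aryl hydrocarbon receptor 1 rose and 2 fell by both adjustments (0.210).

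Signalling and inflammatory lists were mixed. Of 14 feedback targets of ERK, 4 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.215, mean 0.15, median -0.17). The mean of the ERK list was 0.0023 and 0.26 without ZM replicates 2 and 3 and between these without any other library, and it was 0.18, 0.35 and -0.25 in ZM replicates 1, 2 and 3. Of 15 feedback targets of NF-kB 4 rose and 1 fell (5 and 1; 0.148), a list that was called without a filter (0.0445). Of 15 p53 targets, 5 rose and 1 fell by both adjustments (0.148). Of 16 inflammatory cytokines and chemokines, 3 rose and 3 fell (4 and 5 adjusted over the list alone; 0.446), with a mean of -0.14 and a median of 0.02. The mean of that list was -0.37, -0.28 and -0.37 without ZM replicates 1, 2 and 3, -0.32 without Ctrl replicate 3, and -0.18 and -0.11 without Ctrl replicates 1 and 2. The filter was applied anew without each library, so the tested members of this list may differ between these means. For antigen presentation and dendritic cells, 2 of 13 rose and 1 fell by both adjustments (0.161), and for monocytes 0 of 6 rose and 1 fell (0.974). The cytoskeleton and podosome list had 3 risen and 2 fallen genes of 17 (8 and 4 adjusted over the list alone; 0.620), with a mean of -0.07, a median of 0.25 and an upward camera statistic. Without single libraries its mean was from -0.10 (ZM replicate 2) to -0.03 (ZM replicate 3).

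Markers of other bone marrow cell types were mixed. The neutrophil marker that was most abundant over all 6 libraries, Mmp8, was at 22.4 ± 1.64 CPM in Ctrl and 28.6 ± 9.59 CPM in ZM (adjusted p = 0.293), and of 5 tested neutrophil markers 1 rose, namely Csf3r, at 7.25 ± 0.281 CPM in Ctrl and 32.0 ± 21.8 CPM in ZM (0.111 to 0.121 without single Ctrl libraries), and 2 fell by both adjustments (camera adjusted p = 0.510). Of 8 stromal and osteoblast markers 0 rose and 0 fell by both adjustments (0.733), with Runx2 the most abundant at 17.3 ± 0.204 and 12.1 ± 2.10 CPM (adjusted p = 0.0572, with 0.00892 and 0.0356 without ZM replicates 2 and 3 and 0.1401 to 0.198 without any other library). Of 5 endothelial markers 1 fell and 0 rose by both adjustments (0.201), the fallen gene being Kdr, the most abundant of them at 46.3 ± 5.43 and 14.2 ± 6.87 CPM (0.0926 to 0.119 without single Ctrl libraries). The remaining lists had under 5 tested members and no camera test. Kit fell from 2.80 ± 0.632 to 0.752 ± 0.405 CPM (adjusted p = 0.0366) as 1 of 2 fallen among 3 mast cell and basophil markers (3 adjusted over the list alone). Hbb-bs, a haemoglobin chain, fell from 2.29 ± 0.434 to 0.367 ± 0.0648 CPM (adjusted p = 0.00392) as the fallen 1 of 3 erythroid markers (2 adjusted over the list alone). Hbb-bs has a near-identical paralog, so its level is uncertain. Pf4, a platelet chemokine, rose from 6.70 ± 1.70 to 24.2 ± 10.97 CPM (adjusted p = 0.0179) with 2 others of 4 megakaryocyte markers, 3 in all by both adjustments. Cd79b was at 0.376 ± 0.159 and 1.06 ± 0.535 CPM as the 1 tested B cell marker (adjusted p = 0.0904, called over the list alone and at 0.0256 without ZM replicate 2, and 0.153 to 0.268 without any other library). Cd4 was at 2.95 ± 0.410 and 5.10 ± 2.86 CPM (adjusted p = 0.189), where 0 of 3 T and NK cell markers passed by both adjustments. Pf4 lost its call without single Ctrl libraries (0.0653 to 0.0999). So did Kit (0.104 to 0.149, and 0.0889 without ZM replicate 1), whereas Hbb-bs kept it without any single library.

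Shares of counts were compared for 9 classes of genes by exact two-sided permutation tests, in which the smallest p is 0.1. Mitochondrially encoded genes took 3.20% ± 0.0875 of counts in Ctrl and 2.91% ± 0.374 in ZM (exact p = 0.3, Benjamini-Hochberg adjusted 0.45), and ribosomal protein genes 3.89% ± 0.107 and 4.27% ± 0.573 (exact p = 0.4, adjusted 0.45). Haemoglobin genes took 3.5e-04% and 7.0e-05% (exact p = 0.1, adjusted 0.18) and genes without a symbol 0.00200% and 0.00287% (exact p = 0.4, adjusted 0.45). The 20 most abundant genes took 11.04% ± 0.216 and 13.2% ± 1.48, and the 100 most abundant 21.9% ± 0.332 and 24.6% ± 2.26 (exact p = 0.1 and adjusted 0.18 for both). Lyz2, which encodes lysozyme, took 0.795% ± 0.0648 and 2.16% ± 0.797, and Malat1, a nuclear RNA, 0.0915% ± 0.0108 and 0.0485% ± 0.0247 (exact p = 0.1 and adjusted 0.18 for both). The 18S ribosomal RNA entry Rn18s took 0.157% ± 0.0324 and 0.299% ± 0.242 (exact p = 0.5, adjusted 0.5), with 0.565% in ZM replicate 3.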

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

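The halved counts and the limma-voom fit with quality weights were chosen only after the data had been seen. All 1711 called genes kept their direction in every alternative in which they were tested, and no named gene (71) or called list (10) reversed. DESeq2 called 3295 genes (1712 risen, 1583 fallen), quality weights 6622 (3271, 3351; 1263 with a log2 fold of at least 1), glmTreat 302 (70, 232; 289), and a minimum of 1 CPM in all libraries, which tests fewer genes, left 442 with a log2 fold of at least 1. Leaving out 1 library gave 148 to 5023 genes, 31 to 2571 risen, 117 to 2452 fallen and 135 to 1583 with a log2 fold of at least 1; fewer libraries were fitted, the most genes were called without ZM replicate 2, and 41 of 61 named calls ended without at least 1 library. Whether the replicate numbers pair the libraries was not settled. Same-numbered deviations from the group mean correlated at 0.031, 0.047 and 0.107, and the other pairs at -0.137 to 0.089. Ctrl replicate 1 correlated best with ZM replicate 2 (0.089), and Ctrl replicates 2 and 3 with the ZM library of the same number. With 3 libraries per group such small correlations cannot exclude a pairing. With the replicate number as a block, 1679 genes were called, 1360 of them shared with the 1711. The other settings gave 1496 to 2128 genes. At this depth, and with the same dispersion in both groups, the simulated test recovered 52% of genes changed by a log2 fold of 1, so smaller changes were often not detectable.

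List calls depended on the test: 10 in the fit reported, 17 without a filter, 0 with an estimated correlation, 17 with fry and 29 with its mixed test. With the estimated correlation the means of the transcription factor (-0.53), fusion (-0.94) and bone resorption lists (-1.49) were no longer past the threshold, and with quality weights that of the transcription factors (-0.48). The RANK list (-0.15) and the repressors (0.0510) passed with fry and fry's mixed test, and the repressors (0.0522) without a filter.

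The reversed means belonged to lists not called in the fit reported, and the cause was not tested, though CPM limits changed the list members. Leaving out 1 library also repeated the filter, which then kept 16002 to 16062 genes against 15590. List members could therefore differ there too. For repressors the reversed means were -0.0178 without composition factors, -0.0188 with limma-voom, -0.001068 with length offset and block, and -0.11 with quality weights. Leaving out 1 library gave repressor means from -0.19 (ZM replicate 2) to 0.122 (ZM replicate 1), with -0.003764 without ZM replicate 3. The highest repressor mean in any setting was 0.44. The log2 fold of the repressor list member Tnfrsf11b ran from -7.68 to -3.61 when 1 library was left out. For the RANK list the reversed means were 0.0603 with at least 1 CPM and 0.0782 with a 10 CPM background. Both limits left out the member Oscar (log2 fold -3.28 in the fit reported). At the same limits inflammatory genes had 0.13 and 0.0141. For lipid metabolism the reversed means were -0.0625 without composition factors, -0.0125 with at least 1 CPM, -0.0305 with limma-voom, -0.0312 with the block and -0.007179 with offset and block. They were also -0.0253 without the 20 most abundant genes and -0.0605 with quality weights, and leaving out 1 library gave -0.0669 (ZM replicate 3) to 0.0304 (ZM replicate 1). For stromal markers they were 0.05 with the length offset, 0.0565 with offset and block and 0.15 with halved counts. Leaving out 1 library gave stromal means from -0.248 (ZM replicate 3) to 0.13 (ZM replicate 2), with 0.0675 and 0.0739 without Ctrl replicate 1 and ZM replicate 1. For p53 targets the mean was -0.005972 without composition factors and for ERK targets -0.28 without a filter. For G2 and M phase it lay between -0.250 (without ZM replicate 2) and 0.0459 (without ZM replicate 3).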

Other observations

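The iron and complement gene sets, the tests of a larger change in the same direction, of other cell types and of ZM replicate 3 alone, and the Gapdh tests were chosen only after the result was seen.

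Genes of iron handling changed in both directions. The transferrin receptor Tfrc, through which cells take up iron, fell from 216 ± 15.1 to 48.8 ± 21.4 CPM (log2 fold -2.15, edgeR adjusted p = 0.0103), while the exporter Slc40a1 rose by a log2 fold of 2.80. The iron storage proteins rose, Fth1 from 9439 ± 400.2 to 17446 ± 4867 CPM (adjusted p = 0.0296) and Ftl1 from 948 ± 44.3 to 2098 ± 816 CPM (adjusted p = 0.0329), as did the haem-degrading enzyme Hmox1, from 207 ± 10.3 to 427 ± 156 CPM (adjusted p = 0.0334). Steap4, a ferrireductase, and Ncoa4, the ferritin cargo receptor of autophagy, fell from 2.71 ± 0.0693 to 0.561 ± 0.324 CPM and from 181 ± 7.11 to 107 ± 27.4 CPM. Of 20 such genes, 7 rose, 5 fell and 8 were not called. Without the 4 that are in the gene lists or named before, 3 of 16 rose and 5 fell, and the set as such was not tested. All 12 calls were lost without Ctrl replicate 1, 2 or 3, and 7 without ZM replicate 1. With any 1 Ctrl library left out the adjusted p was 0.0529 to 0.0608 for Tfrc, 0.105 to 0.121 for Slc40a1, 0.0796 to 0.0841 for Steap4, 0.124 to 0.141 for Fth1, 0.132 to 0.148 for Ftl1, 0.128 to 0.150 for Hmox1 and 0.1402 to 0.162 for Ncoa4. Without ZM replicate 1 it was 0.0692 for Fth1, 0.0811 for Ftl1, 0.0700 for Hmox1 and 0.0993 for Ncoa4. Counts listed under 2 Ftl1 pseudogenes (8947 against 457380 for Ftl1) leave the level of Ftl1 less certain.

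Of 20 complement genes and innate immune receptors, drawn up once C1qa and C1qb had been seen among the largest rises, 15 rose, 0 fell and 5 were not called by edgeR. Without the 5 that are in the gene lists or named before, 12 of 15 rose and 3 were not called, and the set as such was not tested. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose from 547 ± 7.47 to 1538 ± 270.2 CPM (adjusted p = 0.00235), Nlrp3, an inflammasome sensor, from 40.8 ± 1.90 to 90.9 ± 8.96 CPM (adjusted p = 0.00235) and Tlr1 from 19.2 ± 0.877 to 45.1 ± 8.15 CPM (adjusted p = 0.00470). These 3 kept the call without any single library. C1qc rose from 273 ± 14.0 to 910.5 ± 470.4 CPM, Cfp, which encodes properdin, from 357 ± 23.2 to 917 ± 239 CPM and C3 from 582 ± 12.9 to 959 ± 65.4 CPM. Of the other 12 calls, 12, 11 and 12 were lost without Ctrl replicates 1, 2 and 3 and 2 without ZM replicate 1. For C1qc and C3 the adjusted p was 0.0926 to 0.106 and 0.0566 to 0.0595 without any 1 Ctrl library, and for Cfp it was 0.0555 and 0.0596 without Ctrl replicates 1 and 3.

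The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1711 genes and the highest of the others 1, so 1 of 10 splits called as many. For gene lists the real split called 10 and the highest of the others 12, and 5 of 10 splits called as many. The other splits had unequal numbers of Ctrl libraries on their sides and kept part of the difference of ZM from Ctrl. They are therefore no measure of false calls.

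ZM replicate 3 lay furthest from the controls, with a root mean square log2 difference from the Ctrl mean of 0.794 against 0.45 and 0.383 in ZM replicates 1 and 2, over 9961 genes. The trend with gene length was not the whole of this distance, since the ratio of ZM replicate 3 to the mean of the other ZM libraries was 1.91 before and 1.85 after that trend was removed. A large share of other marrow cells is argued against by 10 markers, of which the highest in ZM replicate 3 was S100a8 at 1.95 CPM (1.41 to 2.14 CPM in Ctrl), but Mmp8, Csf3r and Pf4, not among the 10, were highest in that library at 39.7, 57.2 and 36.9 CPM, so a small share stays open. A larger change in the same direction remains a candidate explanation, as across genes, which are not independent replicates, the length-corrected difference of ZM replicate 3 from the other ZM libraries correlated with their difference from the controls (r = 0.50). RNA of a different quality may also have contributed and was not tested directly, as ZM replicate 3 had the steepest slope of log2 difference on log2 gene length, -0.26 against -0.14 and -0.01 in ZM replicates 1 and 2, and 0.565% of counts in Rn18s against 0.0919% and 0.241%.

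The lower level of bone resorption genes was weighed against the same length trend and against ZM replicate 3. With the length offset the mean log2 fold of the list was -1.49, as without it, which argues against the length trend as the source. Without ZM replicate 3 the mean was -1.35, so that library does not account for the whole of the lower level. The list was chosen before the data were examined. Lower osteoclast formation with ZM is a hypothesis drawn from RNA levels in these libraries alone, in which formation itself was not measured. Counts of multinucleated cells in separate cultures with a named vehicle would decide it, and an effect of the vehicle stays open.

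Gapdh, a common reference gene, had 9768, 12444 and 1421 counts in Ctrl replicates 1, 2 and 3 and 12562, 1325 and 2411 in ZM replicates 1, 2 and 3, a split within both groups. The other 4 Gapdh entries together held at most 89 counts in any library, far under the gap, so the counts did not move to those copies. The other 14 glycolysis genes were higher, not lower, in Ctrl replicate 3 than in Ctrl replicates 1 and 2, by a median log2 difference of 0.11 (0.05 to 0.15). Against ZM replicate 1 their median log2 difference was -0.14 (-0.26 to 0.07) in ZM replicate 2 and -0.19 (-0.49 to 0.14) in ZM replicate 3, where Gapdh differed by -3.20 and -2.19, so a shared fall of glycolysis genes does not account for its split. Reads lost for aligning to several places remain open and were not tested.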
